A study of Caenorhabditis elegans with 91 samples.

How the data were processed

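The values analysed are deposited read counts per gene, 1 table per library, for 91 libraries, of which 64 hold small RNAs and 27 hold mRNA. Per the labels, whole one-day adults, isolated neurons or dissected gonads were lysed in TRIZOL, small RNA libraries were made with NEBNext or TruSeq small RNA kits and mRNA libraries with Nextera XT, and animals grew at 20 °C on OP-50 bacteria unless 25 °C was noted. Which small RNA kit made which library is not given in the sources used here. Per the submitters' processing notes, adapters were trimmed with cutadapt, reads were examined with FastQC, HTSeq counted reads per gene on ce10, and DESeq2 was used for testing, all without versions. The aligner, the annotation and whether strand was used in counting are not given in the sources used here. The tables hold whole numbers of at least 0, so they were taken as counts, and no other scaling by the authors was undone.

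The HTSeq lines for reads outside genes were kept out of totals and tests. Reads in no gene made up 22.2 to 56.4% in whole animals, 61.4 to 71.4% in neuron small RNA, 17.3 to 22.9% in gonad small RNA, 47.5 to 50.9% in neuron mRNA and 50.6 to 54.2% in gonad mRNA, and reads not aligned made up 1.33 to 20.4% over all sets. Gene names were those in the tables, and a list of current names was used only to find renamed genes: 21270 of 21965 genes in the small RNA tables and 29715 of 30199 in the mRNA tables were matched. No genome coordinates were used, since the reference at hand has another build than ce10. Gonad small RNA libraries held 1841973 to 49953667 gene counts and whole-animal libraries 1792 to 31077625, so 1 count was worth 0.0322 CPM in the deepest whole-animal library and 558 CPM in pigEx9 F1 replicate 3. Standard errors and floors of 3 counts per library cover counting error and the spread between these libraries, and nothing upstream of the reads. No library was a copy of another.

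Groups follow the labels' strain, genotype, transgene, generation, tissue and temperature. The whole-animal libraries fall into 6 runs, which the labels do not name. They were inferred from how the records are listed, and served as a technical term only. Among the 11 rde-4 libraries at 20 °C, deviations from the common mean correlated with a median of 0.58 within a run and -0.32 between runs, and 9 of 11 had their nearest neighbour in their own run. Comparisons were made within a run, or with run as a term (pigEx9), except for pigSi3 F3 whole animals, whose run has no control and which were set against all 11 rde-4 libraries. The N2 difference between temperatures compares run 5 with run 1.

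Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, the robust quasi-likelihood F test, and Benjamini-Hochberg adjustment over the genes tested in a comparison, with 0.05 as the threshold. Groups that share a tissue were fitted together. Differences of effects (25 °C against 20 °C, sid-1 mutant against sid-1(+)) were tested as contrasts in 1 model. Gene lists were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01 and a prior count of 3, for lists with at least 5 tested members, adjusted over the lists of a comparison, and again with the correlation estimated.

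The lists were candidate targets of the ERGO-1 pathway, small RNA machinery, chromatin silencing, histones, cytosolic ribosomal proteins, heat shock and stress, immune response, F-box, chemoreceptor and chemosensory, neuropeptide, synaptic vesicle cycle, collagen and major sperm protein genes, and markers of neurons, glia, muscle, intestine, germline, oocytes, sperm and somatic gonad. Lists of microRNA, piRNA and coelomocyte genes, and in small RNA that of mitochondrially encoded genes, had fewer than 5 tested members and were not tested. The mRNA tables held 12 mitochondrially encoded genes. Further lists were drawn from the libraries themselves: genes called in N2 against rde-4 at 25 °C, in WT against rde-4 neurons, in pigEx9 carriers of run 3 (tested in F1 and F3 within run 2 alone), and in gonad small RNA. Each was tested only in other libraries, except in pigSi3 neurons, which share the rde-4 libraries with the list. Their adjusted p covers the lists of this kind in a comparison.

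Comparisons, tests, filter, fixed lists, the rule for named genes and the alternatives were set before the data were examined, apart from 10 alternatives added later. A gene is named where it passed 0.05, its CPM did not overlap between the groups and its mean was at least 5 CPM in the higher group: up to 12 per direction with the largest fold changes in pigSi3 carriers, N2, WT and pigEx9 P0, and up to 5 elsewhere. With 3 libraries against 3, 10% of unchanged genes would not overlap. Always looked at were rde-4, sid-1, saeg-1, saeg-2, egl-4, hrde-1, rde-11, bath-45, C38D9.2 and F15D4.5, and up to 4 members per list with the smallest adjusted p. The genes of a set test and those with the smallest p of a difference were chosen after their values were seen, and so were the genes followed from carriers into F1 and F3.

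Alternatives were DESeq2 1.42.0 with its Wald test, RLE size factors, library totals, no filter or a mean count of at least 50, the 2 compared groups fitted alone, other choices of rde-4 controls, replicate number as a block, and each library left out in turn. Replicate numbers pair the libraries of run 1, where the 9 pairs with equal numbers had correlated deviations (0.24 to 0.49, median 0.31, against -0.21 for other numbers) and 9 of 9 libraries were closest to their own number; this comes from the data and the labels' numbers, not from a stated design. Fold changes that share controls were set beside 20 simulations of unchanged groups with the same sharing.

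The fits were tested on simulated data with known changes in each comparison. For pigSi3 whole animals 54.6% of 2-fold and 91.8% of 4-fold changes were recovered, for pigEx9 P0 80.4 and 97.9%, for pigSi3 gonad small RNA 56.6 and 82.8%, for WT neuron mRNA 1.05 and 11.8% and for pigSi3 gonad mRNA 31.6 and 86.3%. Of 40 lists of unchanged genes per comparison, at most 2 had a camera p under 0.05. The simulated genes were drawn independently of each other, so this does not cover lists whose members vary together.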

Results

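The series measured small RNAs and mRNAs of Caenorhabditis elegans in which RDE-4, a double-stranded RNA binding protein that works with Dicer to make small interfering RNAs, was present everywhere, nowhere, or in neurons alone. The rde-4(ne299) mutant was the reference. In pigSi3 animals this mutant carried an integrated rde-4 transgene driven by the sng-1 promoter, which is active in neurons, while pigEx9 and pigEx10 were extrachromosomal arrays that drove rde-4 from the neuronal promoters sng-1 and rgef-1. P0 denotes animals carrying a transgene, and F1 and F3 denote mutant descendants of such animals that had lost it. Small RNA libraries came from whole animals (47), isolated neurons (6) and dissected gonads (11), and mRNA libraries came from neurons (12) and gonads (15). Groups held 3 libraries each, except the rde-4 mutant in whole animals at 20 °C (11), pigEx9 P0 (6), each neuron mRNA group (4), each neuron small RNA group (2) and each gonad small RNA group (2, with 3 for rde-4). The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

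Counts assigned to genes ran from 735328 to 2530023 per library in neuron small RNA, from 1841973 to 49953667 in gonad small RNA, from 5972135 to 15765852 in neuron mRNA and from 2746062 to 36765116 in gonad mRNA. In whole animals the median was 11013955, and pigEx9 F1 replicate 3 held 1792 counts, the lowest, so that 1 count there was worth 558 CPM (counts scaled to libraries of equal total). The next lowest was pigEx9 F3 replicate 2 with 918317. The deposited values are numbers of reads per gene, and small RNA counts carry neither the length, the class nor the strand of the RNA, so "small RNAs of a gene" below means all small RNA reads counted in it. Levels are CPM scaled by TMM over the libraries fitted together, given as mean ± SD with n libraries, and differences are log2 fold changes with their standard error. For lists, tested with camera, the adjusted p uses a preset correlation between genes, and the estimated-correlation adjusted p uses a correlation estimated from these libraries. Counts over the list alone adjust for the members of the list only. The plot of called genes by comparison shows the number in each direction.

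**Figure D1:**
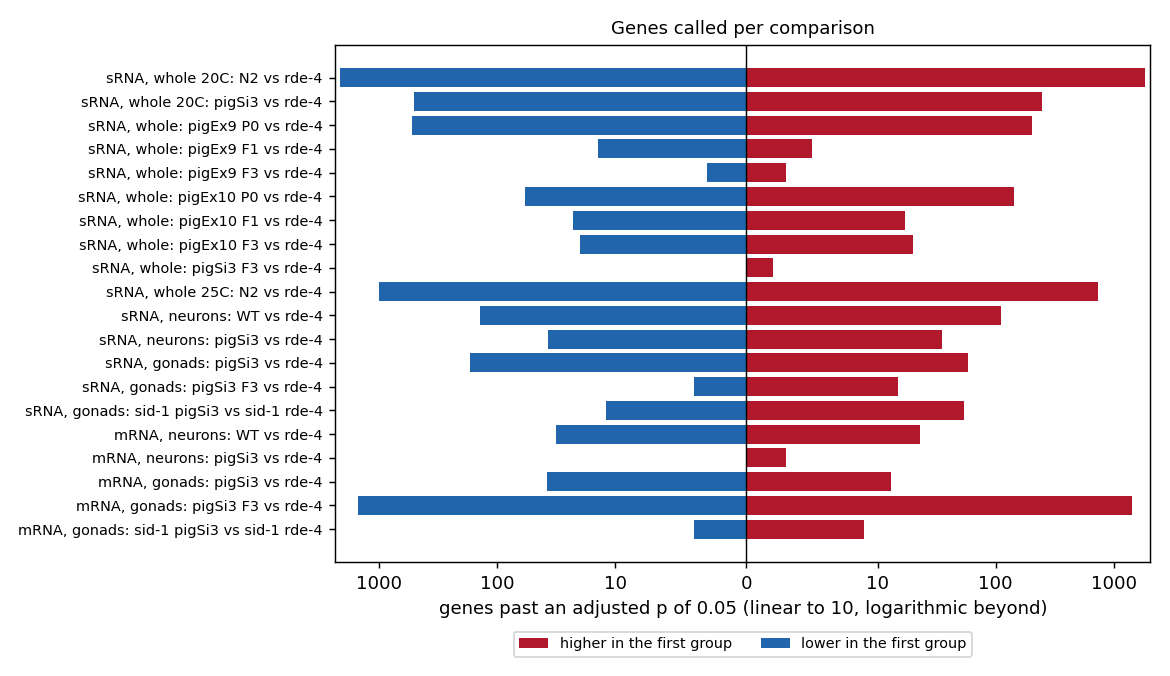
Horizontal bars give the number of genes past an adjusted p of 0.05 (linear to 10 genes, logarithmic beyond) that were higher (red, right) or lower (blue, left) in the first named group of each comparison, sRNA standing for small RNA. The longest bars belong to N2 against rde-4 at 20 °C (1857 higher, 2159 lower) and to gonad mRNA of pigSi3 F3 (1434 higher, 1527 lower), and pigSi3 neurons had 3 mRNA calls.

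The rde-4 gene itself was looked at first, since it distinguishes the strains. In neuron mRNA, rde-4 stood at 2.84 ± 0.891 CPM in the mutant, 16.9 ± 8.17 in wild type (WT) and 299.6 ± 15 in pigSi3 (SD, n = 4 each). The log2 differences from the mutant were 2.56 (SE 0.412, adjusted p = 0.0155) and 6.71 (SE 0.492, adjusted p = 2.08e-05). In gonads, where the transgene promoter is not known to act, rde-4 mRNA was 32.7 ± 3.04 CPM in pigSi3 and 31.5 ± 6.91 in rde-4 (n = 3 each, log2 0.05, adjusted p = 0.981). Mutant libraries of gonads thus still held rde-4 reads, and the count does not tell mutant from intact transcripts. Small RNAs counted in rde-4 were far more abundant in carriers of either array. They stood at 5688 ± 2490 CPM in pigEx9 P0 (n = 6) against 98.9 ± 16.7 in the mutant (n = 5), a log2 difference of 5.78 (SE 0.276, adjusted p = 7.26e-12). Carriers of the other array held 3418 ± 1030 CPM in pigEx10 P0 against 236.2 ± 25.6 (n = 3 each, log2 3.86, adjusted p = 4.54e-07). In the integrated line they were not raised, with 88.1 ± 2 CPM in pigSi3 against 99.2 ± 9.52 in the mutant (n = 3 each, log2 -0.17, adjusted p = 0.425). Descendants that had lost pigEx9 held 235.2 ± 88.2 CPM in F1 (log2 1.74, adjusted p = 0.0137, n = 3 including the failed library) and 159.4 ± 21.7 in F3 (log2 0.92, adjusted p = 0.428). After pigEx10, rde-4 small RNAs in F1 (log2 0.43, adjusted p = 0.865) and F3 (log2 -0.05, adjusted p = 0.997) did not pass the test.

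**Figure D2:**
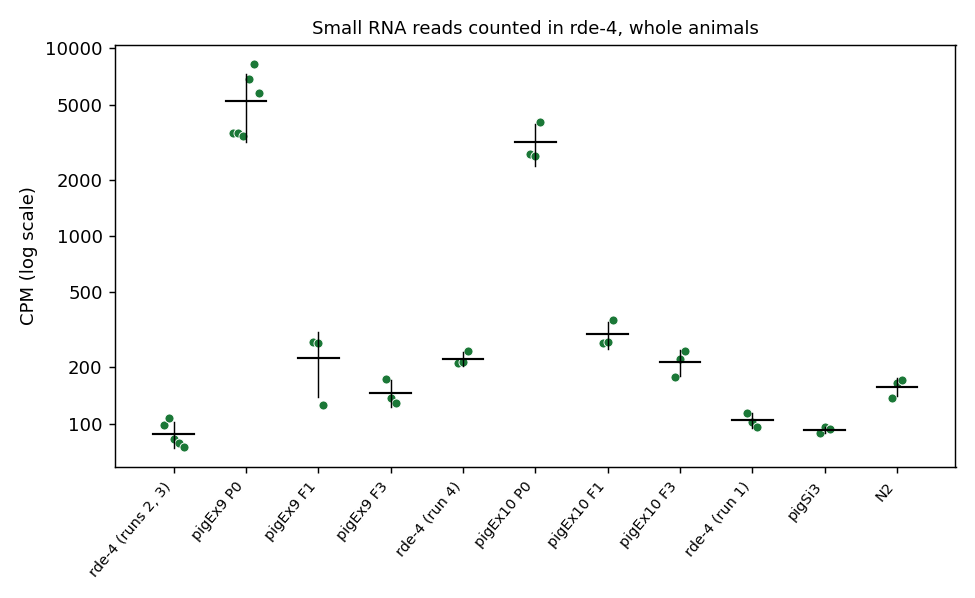
Each point is the level of small RNAs counted in rde-4 in 1 whole-animal library (CPM, logarithmic axis), with the group mean (horizontal line) and SD (vertical line), scaled over all whole-animal libraries at once and so unlike the means in the text. pigEx9 F1 has a library with 1 count in rde-4, the lowest of its points, at 125.3 CPM after TMM scaling, which enlarges its total. The 6 pigEx9 P0 libraries lie between 3409 and 8276 CPM and the 3 pigEx10 P0 libraries between 2681 and 4073, above every library of rde-4, F1 and F3.

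Which small RNAs need RDE-4 was asked in whole animals at 20 °C. Small RNAs of several genes were almost absent from the mutant. Y17D7B.4 had 964.5 ± 52.6 CPM in wild-type N2 and 1.98 ± 0.0851 in rde-4 (log2 8.92, SE 0.139, adjusted p = 3.02e-11), and C36A4.11 (843 against 1.22 CPM), Y47H10A.5 (log2 10.06), H09G03.1 (log2 9.64) and W04B5.1 (log2 8.93) behaved alike. Small RNAs of F56D6.16 went from 567 CPM in N2 to 0.067 in the mutant. Those of linc-121 were at 0 counts in all 3 mutant libraries and at least 93.1-fold higher in N2, against a floor of 3 counts per library. A second set was more abundant in the mutant. Small RNAs of dpf-6, a dipeptidyl peptidase family gene, rose in the mutant from 0.571 ± 0.251 to 629.6 ± 89.2 CPM (log2 of N2 over rde-4 -10.06, SE 0.271, adjusted p = 1.48e-09). Those of T28F2.1 (-6.23), T23F6.3 (-5.71), ndx-1, a Nudix hydrolase gene (-5.60), crtc-1, a CREB coactivator gene (-5.03), the cAMP phosphodiesterase gene pde-4 (-4.89) and rgs-4, a regulator of G protein signalling (-4.78), were likewise lower in N2. T23F6.3 varied between rde-4 runs, at 385 CPM in run 1 and 11.3 in run 4, against 7.7 in N2 (scaled over all whole-animal libraries).

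saeg-2, which encodes a nuclear protein that acts downstream of the cGMP-dependent protein kinase EGL-4, had 3541 ± 462 CPM of small RNAs in N2 and 455.8 ± 16.3 in rde-4 at 20 °C (n = 3 each), a log2 difference of 2.96 (SE 0.137, adjusted p = 9.24e-08). Its partner saeg-1 was also higher in N2 (log2 1.22, adjusted p = 0.000324), as were F15D4.5 (0.64, adjusted p = 0.00681) and bath-45 (0.57, adjusted p = 0.00683). Small RNAs of sid-1 (0.13, adjusted p = 0.328), C38D9.2 (0.28, adjusted p = 0.118) and B0564.11, now named rde-11 (0.06, adjusted p = 0.67), did not pass the test, although C38D9.2 did in the paired fit with replicate number as a block (log2 0.27, adjusted p = 0.0285).

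Among the gene lists, 14 of 16 candidate targets of the ERGO-1 pathway, which makes 26G small RNAs in oocytes and embryos, were higher in N2 (15 over the list alone). C44B11.6 (log2 7.14), ZK402.3 (7.47) and W04B5.2 (6.53) were among them, and the list median was 5.64 (camera adjusted p = 6.16e-18, estimated-correlation adjusted p = 0.187). Small RNA pathway genes had 21 higher and 3 lower of 64 (24 and 4 over the list alone, adjusted p = 0.000161, estimated-correlation adjusted p = 0.369), including eri-6 (0.74), rsd-2 (0.67) and alg-2 (0.69), with drh-2 lower (-1.86). Chromatin silencing genes had 7 of 23 higher (10, with 1 lower, over the list alone, adjusted p = 0.00904, estimated-correlation adjusted p = 0.594), met-1 at 0.61 among them. Germline markers had 12 of 24 higher (15 over the list alone, adjusted p = 0.000161, estimated-correlation adjusted p = 0.388), such as cgh-1 (0.64), mex-5 (0.62) and glp-1 (0.38). In contrast 55 of 234 chemoreceptor and chemosensory genes were lower and 11 higher (51 and 10 over the list alone, adjusted p = 0.000843, estimated-correlation adjusted p = 0.199). Of 43 collagens 16 were lower and 3 higher (22 and 4 over the list alone, adjusted p = 0.00024, estimated-correlation adjusted p = 0.369). Neuron markers had 6 of 18 lower and 1 higher (adjusted p = 0.00697, estimated-correlation adjusted p = 0.506), including ida-1 (-1.25), ric-4 (-1.69) and unc-31 (-0.96).

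N2 and rde-4 differed in 4016 of 12800 genes tested with edgeR's quasi-likelihood test at 20 °C, 1857 higher and 2159 lower in N2. Scaling by library totals shifted the median of all genes by -0.248 and gave 618 higher and 3886 lower. Under it the medians of the germline markers (0.09), the chromatin list (0.05) and the small RNA pathway list (0.01) lay close to 0, and glp-1 and mex-5 did not pass. The paired fit with replicate number as a block called 3118 higher and 2896 lower. Without rde-4 replicate 1 the count was 2657.

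Neuronal RDE-4 in the integrated line changed small RNAs of 750 genes in whole animals at 20 °C, 246 higher and 504 lower in pigSi3 than in rde-4. saeg-2 was among the strongest, with 2475 ± 258 CPM in pigSi3 against 455.8 ± 16.3 in rde-4 (n = 3 each, log2 2.44, adjusted p = 3.22e-06). Its partner saeg-1 rose to 375.6 ± 59.9 from 175.1 ± 31.9 CPM (log2 1.1, adjusted p = 0.00242). jmjc-1, which encodes a JmjC domain protein, reached 1102 ± 98.5 CPM from 152.4 ± 7.64 (log2 2.85, SE 0.11, adjusted p = 1.27e-07), and Y110A2AL.1 reached 608 ± 135 from 4.89 ± 0.797 (log2 6.97, adjusted p = 8.3e-08). tbc-8, a Rab GTPase-activating protein gene of dense core vesicle biology, rose by 3.02, C53D5.5 by 3.32, C27D8.3 by 3.096 and W06A11.4 by 2.48. Scaled over all whole-animal libraries, C53D5.5 had 199 CPM in pigSi3 and 13.1 in N2. Its rde-4 run means, without a transgene, ranged from 19.9 to 253 CPM. Genes whose small RNAs the rde-4 libraries of run 1 had in excess came down towards the N2 level: T28F2.1 (log2 -5.88), T23F6.3 (-4.93), pde-4 (-4.30, 2.85 ± 0.344 CPM against 56.3 ± 8.71), the neuropeptide receptor gene npr-20 (-4.17) and the innexin gene inx-13 (-2.78). For T23F6.3, rde-4 run means ranged from 11.3 to 385 CPM without a transgene, against 12.6 in pigSi3 (scaled over all whole-animal libraries). Against all 11 rde-4 libraries, of several runs, jmjc-1 (0.41, adjusted p = 0.821), tbc-8 (1.22, adjusted p = 0.32), C53D5.5 (1.05, adjusted p = 0.522), C27D8.3 (1.52, adjusted p = 0.265), inx-13 (-1.82, adjusted p = 0.147) and T23F6.3 (-4.16, adjusted p = 0.0669) did not pass. They passed in every other alternative, and saeg-2, saeg-1, Y110A2AL.1, W06A11.4, T28F2.1, pde-4 and npr-20 passed in all.

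Histone genes stood out among the lists in pigSi3 whole animals, with 14 of 63 higher and 1 lower (30 and 5 over the list alone, median 0.54, camera adjusted p = 2.16e-09, estimated-correlation adjusted p = 0.434). Examples were his-16 (log2 2.80), his-44 (1.82) and his-63 (1.39), but copies of histone genes are near-identical, so reads cannot be placed in them with certainty. Of the 16 ERGO-1 candidates 5 rose (6 over the list alone, adjusted p = 0.000638, estimated-correlation adjusted p = 0.434), but to a small part of the N2 level. C36A4.11 reached 15.9 ± 0.651 CPM, C44B11.6 21.4 CPM (log2 1.38), K02E2.6 37.4 CPM (1.27) and Y17D7B.4 3.44 CPM (log2 0.80, adjusted p = 0.0065). Collagens had 6 of 43 lower and 1 higher (12 and 1 over the list alone, adjusted p = 3.75e-05, estimated-correlation adjusted p = 0.434). Chemoreceptors had 14 of 234 lower and 4 higher (18 and 6 over the list alone, adjusted p = 0.0142, estimated-correlation adjusted p = 0.434), str-238 (-1.93) among them. Against all 11 rde-4 libraries Y17D7B.4 (adjusted p = 0.163) and str-238 (adjusted p = 0.107) did not pass. Neuropeptide genes did not pass (adjusted p = 0.0539) but did in the paired fit with the block (adjusted p = 0.0212). Lists drawn from other libraries moved in part with pigSi3. Of 732 genes higher in N2 than rde-4 at 25 °C, 62 were higher and 19 lower in pigSi3 (adjusted p = 4.41e-05, estimated-correlation adjusted p = 0.327). Of 971 genes lower at 25 °C, 141 were lower and 22 higher (adjusted p = 1.97e-05, estimated-correlation adjusted p = 0.12). Of 108 genes higher in WT than in rde-4 neurons 17 rose and 5 fell (adjusted p = 0.000291, estimated-correlation adjusted p = 0.327). Of 141 genes lower there 42 fell and 9 rose (adjusted p = 4.03e-08, estimated-correlation adjusted p = 0.327).

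In run 1, which holds the N2, rde-4 and pigSi3 libraries at 20 °C and where equal replicate numbers pair the samples, a fit with the number as a block called 1554 genes for pigSi3. Leaving out a library gave 369 (without rde-4 replicate 2) to 603 genes. It gave 419 without rde-4 replicate 1, 396 and 477 without pigSi3 replicates 1 and 3, and a value between these without pigSi3 replicate 2. Fold changes of N2 and of pigSi3, both against the same 3 rde-4 libraries, correlated across 12800 genes with r = 0.43 (0.49 in simulations of unchanged groups) and a covariance of 0.21 (0.0376 simulated). Both were higher in 106 genes (35.7 for independent lists), both lower in 374 (85), and they pointed opposite ways in 54, where part of the excess may come from the shared controls.

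**Figure D3:**
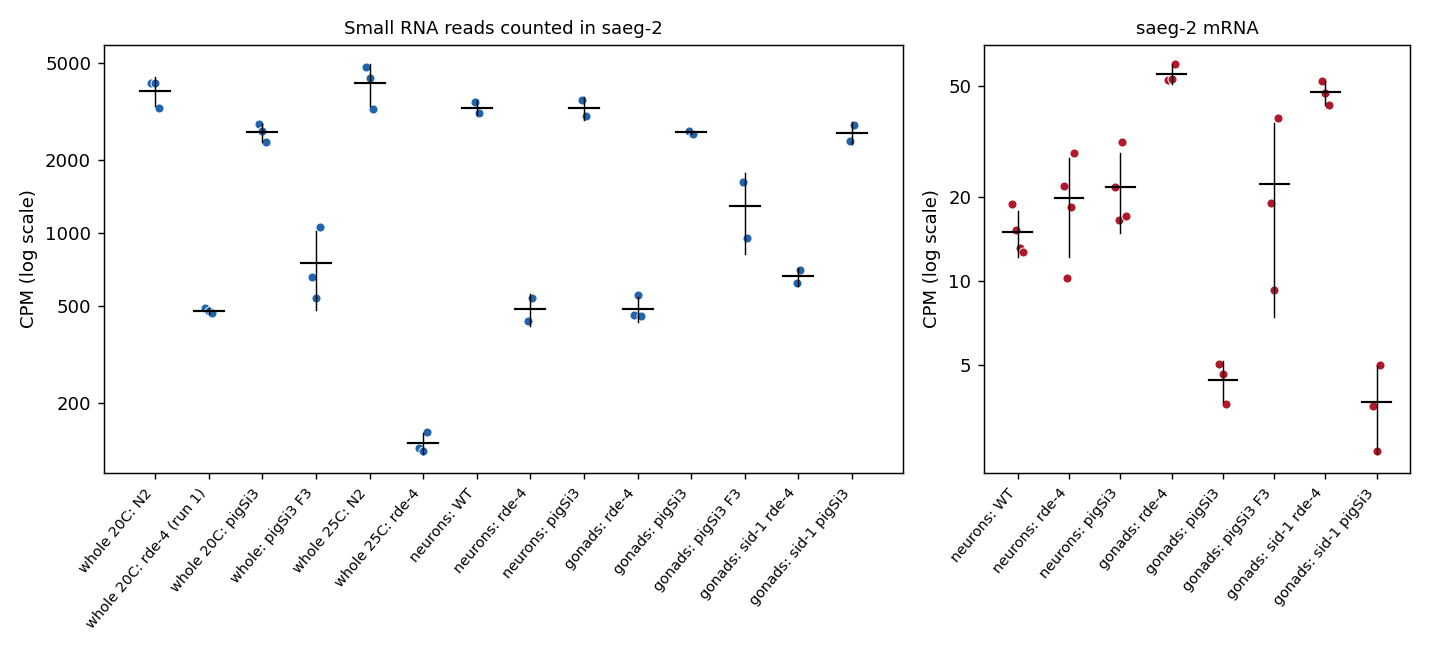
Points give saeg-2 per library as small RNA (left, CPM, logarithmic axis) and as mRNA (right, CPM, logarithmic axis), with group means (horizontal lines) and SDs (vertical lines), scaled over all libraries of a tissue and so unlike the means in the text. Small RNAs lie between 2372 and 4835 CPM in N2, WT and pigSi3 and below 704 CPM in rde-4 and sid-1 rde-4, while gonad mRNA lies between 42.8 and 59.7 CPM in rde-4 and sid-1 rde-4 and between 2.46 and 5.05 in pigSi3 with or without sid-1.

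Carriers of pigEx9 regained small RNAs that the mutant lacks. Y47H10A.5 reached 1068 ± 127 CPM in pigEx9 P0 (n = 6) against 1.31 ± 0.79 in rde-4 (n = 5, log2 9.63), Y17D7B.4 800 against 3.01 CPM (log2 8.05) and F56D6.16 556 against 0.261 CPM. gpd-2, a glyceraldehyde-3-phosphate dehydrogenase gene, rose from 1.84 ± 0.678 to 136.3 ± 70.3 CPM (log2 6.298, SE 0.216, adjusted p = 4.19e-14). Small RNAs of daf-7, the TGF-beta ligand gene of dauer control, were lower (4.77 ± 2.33 against 39.5 ± 30.6 CPM, log2 -3.12, adjusted p = 9.51e-07). So were those of asah-1, an acid ceramidase gene (-3.08), the axon guidance receptor gene eva-1 (-3.02), Y77E11A.2 (-3.07) and crtc-1 (-2.27). saeg-2 small RNAs were at 897 ± 530 CPM against 523 ± 59.8 and did not pass the test (log2 0.71, adjusted p = 0.127). It did with all 11 rde-4 libraries and without P0 replicate 6, and the log2 difference was 0.13 in run 2 alone and 1.26 in run 3 alone (over all alternatives adjusted p 0.0267 to 0.762).

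Of 16 ERGO-1 candidates 9 rose and 1 fell in pigEx9 P0 (camera adjusted p = 7.89e-31, estimated-correlation adjusted p = 0.0669), such as C44B11.6 (log2 5.33), W04B5.2 (5.09) and K02E2.6 (4.66, 550.5 ± 186 against 22.6 ± 7.38 CPM). F-box genes of the fbxa, fbxb and fbxc families had 30 of 227 lower and 3 higher (47 and 3 over the list alone, adjusted p = 0.000198, estimated-correlation adjusted p = 0.914). Of 93 genes higher in WT than in rde-4 neurons 35 rose and 9 fell (median 0.21, adjusted p = 2.64e-52, estimated-correlation adjusted p = 0.0575). In all 730 of 10767 genes passed, 203 higher and 527 lower, in a fit with the inferred run as a term, with 1523 in run 2 alone, 165 in run 3 alone and 485 without rde-4 replicate 4. No paired fit was possible here, since the groups of a run share at most 1 replicate number. crtc-1 did not pass in run 3 alone.

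After pigEx9 was lost, 19 genes passed in F1 (5 higher, 14 lower), rde-4 among them. Lower were asah-1 (log2 -3.64, adjusted p = 0.0137), ZK1010.5 (-3.50, adjusted p = 0.00353), daf-7, followed here because of its change in carriers (-2.01, adjusted p = 0.0295), C18D4.6 (-1.80, adjusted p = 0.00539) and kal-1, the gene of an anosmin-like protein of neuronal branching (-1.64, adjusted p = 0.0155). In F3, 6 genes passed. Higher were 3 (W03C9.6 at log2 1.74, adjusted p = 0.000396, gpd-2 at 1.94 and C46G7.5 at 1.57) and lower 3 (ZK1010.5 at -3.81, adjusted p = 0.000797, C18D4.6 at -1.46 and F32B5.3 at -1.43). saeg-2 was level with the mutant in F1 (log2 0.20, adjusted p = 0.982) and F3 (518 ± 41.8 against 523 ± 59.8 CPM, log2 0.35, adjusted p = 1, 0.02 in run 2 alone). The means cover the controls of runs 2 and 3, while F1 and F3 lie in run 2 and the log2 difference comes from the fit with run as a term. None of the fixed lists passed in F1 of 20 tested, and 4 passed in F3: major sperm protein genes (lower, adjusted p = 4.12e-06, estimated-correlation adjusted p = 0.525), sperm markers (lower, adjusted p = 0.00484, estimated-correlation adjusted p = 0.802), intestine markers (higher, adjusted p = 0.00501, estimated-correlation adjusted p = 0.996) and ERGO-1 candidates (higher, adjusted p = 0.00535, estimated-correlation adjusted p = 0.996). Of the lists drawn from 25 °C and from neurons, genes higher in WT neurons passed in F1 (adjusted p = 0.0219, estimated-correlation adjusted p = 0.978). In F3 all 4 passed (estimated-correlation adjusted p = 0.748 for each). Genes higher and lower in N2 at 25 °C went up and down (adjusted p = 0.0151 and 0.00154), while genes higher and genes lower in WT neurons both went up (adjusted p = 0.00666 and 0.0276).

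A list of 60 genes lower in run 3 carriers was tested in F1 within run 2 alone, so that no library is shared, and had 17 lower and 4 higher (adjusted p = 0.00118, estimated-correlation adjusted p = 0.896). The 105 genes higher in those carriers did not pass as a list in F1 (5 higher, 7 lower, adjusted p = 0.278) or F3 (1 higher, 7 lower, adjusted p = 0.412). Nor did the 60 lower ones in F3 (2 higher, 5 lower, adjusted p = 0.319). P0 and F1 fold changes correlated with r = 0.70 (0.48 simulated) and a covariance of 0.172 (0.0401 simulated), with part of the excess possibly owed to shared controls. In run 2 alone 376 and 300 genes passed in F1 and F3, and with only the 2 groups fitted 417 and 64. The F1 and F3 counts depended on single libraries: leaving out pigEx9 F1 replicate 1, 2 or 3 gave 0, 1 or 12 genes in F1. Without both shallow libraries the counts were 7 in F1 and 2 in F3. In F3 they were 3 without F3 replicate 1, 3 without F3 replicate 2, 2 without rde-4 replicate 5 and 12 without rde-4 replicate 8. Every gene named for F1 lost its call without F1 replicate 1 or without replicate 2. In F3 C46G7.5 lost it in 10 of 17 alternatives, F32B5.3 in 9 of 15, C18D4.6 in 7 of 17, gpd-2 in 6 of 17 and W03C9.6 with all 11 controls, and ZK1010.5 in none. rde-4, where 1 of the 3 values rests on 1 count, also lost it without the shallow libraries and with all 11 controls (over all alternatives log2 0.97 to 2.02, adjusted p up to 0.649).

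The array driven by the rgef-1 promoter also gave gains in its carriers. W04B5.1 had 465 ± 20.3 CPM in pigEx10 P0 and 0.4657 ± 0.214 in rde-4 (n = 3 each, log2 9.78, SE 0.175, adjusted p = 3.61e-12), and Y47H10A.5 (10.14) and Y17D7B.4 (8.86) rose alike. T09B9.2, a solute carrier gene now named slc-17.9, had 21 ± 5.13 CPM and 0 counts in all 3 rde-4 libraries, at least 41.1-fold higher. Lower were C55C3.7 (log2 -6.26), Y59C2A.1 (-3.56), C53D5.5 (-3.49, 23.9 ± 2.54 against 268.5 ± 14.4 CPM) and eva-1 (-2.67). Small RNAs of saeg-2 were at the mutant level (369.8 ± 38.1 against 393.3 ± 53.6 CPM, log2 -0.09, adjusted p = 0.799).

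Of 16 ERGO-1 candidates 10 rose in pigEx10 P0 (12 over the list alone, with 1 lower), with a median of 3.85, and this call held with an estimated correlation (adjusted p = 2.26e-23, estimated-correlation adjusted p = 8.18e-05). C44B11.6 (log2 6.54) and K02E2.6 (5.97) were among them. Of the genes higher in WT than in rde-4 neurons 45 rose (median 0.62, adjusted p = 4.52e-42, estimated-correlation adjusted p = 0.00137). The 105 genes higher in pigEx9 carriers of run 3 gave 29 higher (adjusted p = 1.37e-28, estimated-correlation adjusted p = 0.00845), and the 60 lower genes gave 10 lower (adjusted p = 5.1e-11, estimated-correlation adjusted p = 0.0454). In total 202 of 11252 genes passed (144 higher, 58 lower), with 664 when all 11 rde-4 libraries served as controls, and 123 without rde-4 replicate 10. With all 11, C55C3.7 (adjusted p = 0.0858), Y59C2A.1 (adjusted p = 0.112), C53D5.5 (adjusted p = 0.155) and eva-1 (adjusted p = 0.11) did not pass, though they did in every other alternative.

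In pigEx10 F1 and F3 none of the genes higher in WT neurons was called higher (adjusted p = 0.552 in F1, 0.679 in F3). The 60 genes lower in pigEx9 carriers of run 3 had 5 lower in F1 (adjusted p = 3.18e-09, estimated-correlation adjusted p = 0.0508) and 4 lower in F3 (adjusted p = 4.63e-05, estimated-correlation adjusted p = 0.159), none higher. What passed were 40 genes in each generation (17 higher and 23 lower in F1, 20 and 20 in F3), largely the ones seen in carriers. Lower were C55C3.7 (log2 -6.15 in F1, -5.82 in F3), Y59C2A.1 (-3.53 and -3.49), and C53D5.5 (-3.20 and -2.87). Y39B6A.41 (3.84 and 4.01), T23F6.3 (3.93 and 3.41) and cor-1, the coronin gene (1.68 and 2.02), were higher. F1 and F3 calls overlapped in 13 higher (0.0302 for independent lists) and 15 lower genes (0.0409), with a covariance of 0.128 (0.0601 simulated) and part of the excess possibly owed to shared controls. saeg-2 was at the mutant level in F1 (log2 -0.06, adjusted p = 1) and F3 (-0.07, adjusted p = 0.982). Most of these calls rest on the 3 controls of the same run: with all 11 rde-4 libraries, 3 genes passed in F1 and 2 in F3. Y39B6A.41 was among them and passed in every alternative (adjusted p up to 0.00393 and 0.0017), while T23F6.3 turned to -0.33 and -0.85. Without rde-4 replicate 10 the counts were 19 and 12, without replicate 11 they were 19 and 17. Without rde-4 replicate 9 F1 gave 61, without F1 replicates 1 and 2 it gave 22 and 23, and without F3 replicate 2 F3 gave 22.

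Whole pigSi3 F3 animals, which fall in an inferred run without controls, had a mean of 762 ± 279 CPM of saeg-2 small RNAs (n = 3) against 458.5 ± 61 in the mutant (n = 11). This did not pass the test (log2 0.73, SE 0.171, adjusted p = 0.141). It did with DESeq2 and against rde-4 replicates 9 to 11 alone (over all alternatives log2 0.4 to 0.93, adjusted p 0.0163 to 1). saeg-1 did not pass (0.44, adjusted p = 0.29), but did against rde-4 replicates 9 to 11. W06A11.4 (log2 1.52, 273 ± 135 against 94.8 ± 12.7 CPM, adjusted p = 0.014) and C05C9.1 (2.57, 19.43 ± 7.96 against 3.24 ± 1.57 CPM, adjusted p = 0.0144) were the 2 genes called, both higher. Run and group cannot be told apart here, and the count depended on the controls, with 0 genes against rde-4 replicates 1 to 3 (edgeR), 27 against 4 and 5, 2945 against 6 to 8 and 2936 against 9 to 11. Without F3 replicates 1 and 3 it was 4 and 1, and without rde-4 replicates 3 and 11 it was 10 and 4.

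At 25 °C, saeg-2 small RNAs stood at 3097 ± 694 CPM in N2 and 108.9 ± 12.8 in rde-4 (n = 3 each, log2 4.83, SE 0.319, adjusted p = 9.97e-05). saeg-1 (1.57, adjusted p = 0.0193) and sid-1, the gene of a double-stranded RNA importer (0.90, adjusted p = 0.0476), were higher in N2 too. W04B5.1 (log2 9.19) and Y47H10A.5 (8.76) were again lost in the mutant, while dpf-6 (-10.29, 0.372 ± 0.308 against 474.6 ± 127 CPM), ndx-1 (-6.47), T28F2.1 (-6.45) and inx-13 (-6.08) were gained. ERGO-1 candidates had 12 of 16 higher in N2 (14 over the list alone, adjusted p = 1e-13, estimated-correlation adjusted p = 0.61). Histone genes had 23 of 58 lower in N2 and 1 higher (29 and 2 over the list alone, adjusted p = 2.78e-06, estimated-correlation adjusted p = 0.61), his-67 at -2.42 and his-68 at -2.57. Of 10524 genes 1738 passed, 734 higher and 1004 lower (614 and 1287 with library totals), with 815 without N2 replicate 2 and 962 and 1068 without rde-4 replicates 2 and 1. saeg-1 did not pass without either of these, and sid-1 in 6 of 13 alternatives: a mean count of at least 50, the replicate block, and without N2 replicate 1 or 2 or rde-4 replicate 1 or 2 (over all log2 0.78 to 1.1, adjusted p up to 0.16).

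The 25 °C result carried over to 20 °C animals, which share no library with it. Of 732 genes higher in N2 at 25 °C, 412 were higher and 12 lower at 20 °C (median 0.52, adjusted p = 1.41e-30, estimated-correlation adjusted p = 0.0334). Of 971 lower ones 628 were lower and 7 higher (median -0.97, adjusted p = 8.14e-38, estimated-correlation adjusted p = 0.000674). The size of the difference itself changed with temperature in 272 of 12762 genes (164 with a higher and 108 with a lower log2 ratio at 25 °C), and saeg-2 was 1.91 higher at 25 °C (SE 0.287, adjusted p = 0.00607). Chosen after their values were seen, gas-1, a mitochondrial complex I gene (2.65), H09G03.1 (-5.90), F58F9.1 (-5.30) and B0001.6 (-3.69) had the smallest adjusted p of the difference. Histone genes had 6 of 61 lower at 25 °C (11 over the list alone, adjusted p = 7.39e-07, estimated-correlation adjusted p = 0.982). The temperatures fall in different inferred runs and cannot be told apart from them. Leaving out a library raised the count to 572 (without rde-4 at 25 °C, replicate 3) or brought it below the main one, lowest without rde-4 at 20 °C, replicate 2.

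Isolated neurons without RDE-4 also lacked small RNAs of several of these genes. In WT neurons saeg-2 small RNAs were at 3285 ± 192 CPM against 504 ± 86.7 in rde-4 neurons (n = 2 each, log2 2.70, SE 0.163, adjusted p = 2.74e-09), whereas saeg-1 did not pass (0.30, adjusted p = 0.483). W04B5.2 had 1803 ± 32.1 against 21 ± 1.56 CPM (log2 6.41, adjusted p = 1.9e-11), ZK402.3 7.56, C44B11.6 8.02 and K02E2.6 7.003. F58F9.1 had 227.3 ± 43.1 CPM and no count in either rde-4 library, at least 88.7-fold higher against the floor of 3 counts per library. dpf-6 had 0 counts in both WT libraries against 546.6 ± 28.4 CPM, at least 271-fold lower. pde-4 (-4.27), ndx-1 (-3.69) and Y39A1A.9, now named meic-1 (-4.92), were lower in WT. ERGO-1 candidates had 13 of 16 higher (16 over the list alone, median 5.56, adjusted p = 4.39e-32, estimated-correlation adjusted p = 0.0891). Neuropeptide genes had 3 of 11 lower (6, with 1 higher, over the list alone, adjusted p = 0.00211, estimated-correlation adjusted p = 0.409), with ins-5 at -1.27 and nlp-24 at -2.41. Of 7537 genes 252 passed, 111 higher and 141 lower, with 142 and 149 without WT replicates 2 and 1 and 432 without rde-4 replicate 1. C44B11.6, K02E2.6 and nlp-24 did not pass without rde-4 replicate 2, K02E2.6 not without rde-4 replicate 1 and nlp-24 not without WT replicate 1 or 2.

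Neurons of pigSi3 regained saeg-2 small RNAs, at 3289 ± 484 CPM (n = 2, log2 2.71 over rde-4, adjusted p = 1.17e-08). W04B5.2 reached 1183 ± 317 CPM (log2 5.796), C44B11.6 2328 ± 974 (6.85) and K02E2.6 rose by 5.66. Y110A2AL.1 rose to 843.7 ± 115 from 12.8 ± 3 CPM (log2 6.06), and rab-3, the synaptic vesicle GTPase gene, rose by 1.76 (adjusted p = 8.22e-05). F58F9.1 was at 188.5 ± 14.6 CPM. Lower were pde-4 (-3.41), ndx-1 (-3.002), Y39A1A.9 (-4.09) and npr-20, at 0 counts in both pigSi3 libraries against 12.5 ± 0.578 CPM, at least 4.67-fold lower. Of 16 ERGO-1 candidates 3 rose (median 0.25, adjusted p = 5.17e-05, estimated-correlation adjusted p = 0.555). In all 72 of 7537 genes passed (35 higher, 37 lower), with 111 without pigSi3 replicate 2. C44B11.6 and K02E2.6 did not pass with library totals or without rde-4 replicate 1 or 2, and npr-20 not with DESeq2 or without pigSi3 or rde-4 replicate 2. Of 111 genes higher in WT neurons 26 rose in pigSi3 (adjusted p = 1.29e-19, estimated-correlation adjusted p = 0.0462) and of 141 lower ones 28 fell (median -0.56, adjusted p = 6.16e-29, estimated-correlation adjusted p = 0.0794), though these lists share their controls with the test. Fold changes correlated with r = 0.48 (0.52 simulated), 67.4% had the same sign (67.2% simulated), and the covariance was 0.229 against 0.0884 simulated, where part of the excess may come from the shared controls.

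Gonads of animals with RDE-4 in neurons alone also changed. saeg-2 small RNAs in pigSi3 gonads were at 2566 ± 66.6 CPM (n = 2) against 490 ± 55.6 in rde-4 gonads (n = 3, log2 2.39, SE 0.219, adjusted p = 0.000427), and saeg-1 was higher too (1.23, adjusted p = 0.0212). Higher as well were Y110A2AL.1 (log2 5.99), the nuclear receptor gene nhr-64 (4.02), the neuropeptide-like gene nlp-40 (4), the heat shock factor gene hsf-2 (3.95), the serotonin receptor gene ser-5 (2.13) and the microRNA Argonaute gene alg-1 (1.56) with its partner ain-1 (1.105). pde-4 fell to 1.86 ± 0.461 from 69.1 ± 6.61 CPM (log2 -5.24, adjusted p = 1.01e-06) and ndx-1 to 26.5 ± 1.02 from 232.5 ± 4.8 (log2 -3.13). C55C3.7 (-7.89), the prohormone convertase gene aex-5 (-4.03), npr-20 (-3.72), cor-1 (-3.58) and the homeobox gene irx-1 (-3.37) fell with them. In whole rde-4 animals, without a transgene, run means ranged from 1.83 to 109 CPM for C55C3.7 and from 24.7 to 146 for cor-1. Histone genes had 6 of 62 higher (21, with 1 lower, over the list alone, median 0.51, adjusted p = 3.61e-11, estimated-correlation adjusted p = 0.141), for example his-45 (2.39) and his-63 (1.84). Of 882 genes lower in N2 at 25 °C 65 were lower and 3 higher in pigSi3 gonads (median -0.37, adjusted p = 6.76e-10, estimated-correlation adjusted p = 0.0153). Of 11517 genes 228 passed (59 higher, 169 lower), with 33 and 60 without pigSi3 replicates 1 and 2, and 109 and 135 without rde-4 replicates 1 and 3, with a value between these without replicate 2. Of the genes named here saeg-2, nhr-64, hsf-2, ser-5, pde-4, ndx-1, aex-5, irx-1 and his-45 passed in every alternative.

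In gonads of pigSi3 F3, which had lost the transgene, saeg-2 small RNAs were at 1307 ± 528 CPM (n = 2, log2 1.41 over rde-4, SE 0.216, adjusted p = 0.0442), between the mutant and the carriers. saeg-1 did not pass (1.05, adjusted p = 0.0858), but did with DESeq2, with no filter and without F3 replicate 1. The cuticlin-like gene cutl-14 (2.90), his-61 (1.54), his-45 (2.56), his-44 (2.27) and fbxa-193 (2.34) were higher, and T28F2.2 (-2.29), lab-1, a gene of meiotic chromosome cohesion (-0.81), and mrpl-11 (-0.87) were lower. The 882 genes lower in N2 at 25 °C did not pass (median 0.10, adjusted p = 0.052), nor did genes higher in WT neurons (adjusted p = 0.405). The 706 genes higher in N2 at 25 °C went up (median 0.27, adjusted p = 3.27e-05, estimated-correlation adjusted p = 0.424). Genes lower in WT neurons also went up (median 0.48, adjusted p = 1.33e-06, estimated-correlation adjusted p = 0.424), though down in pigSi3 gonads (adjusted p = 2.11e-06, estimated-correlation adjusted p = 0.444). Histone genes had 5 of 62 higher (36 over the list alone, median 0.76, adjusted p = 2.2e-16, estimated-correlation adjusted p = 0.0557). Only 19 genes passed (15 higher, 4 lower), and the count was unsteady. It was 8 higher and 8 lower with library totals, under which the median of all genes shifted by -0.184. It was 0 without rde-4 replicate 1, 3 without replicate 2 or 3, 7 without F3 replicate 2 and 3997 without F3 replicate 1, the shallowest. Each of these last 2 leaves 1 F3 library and takes the spread from the other groups, and the 3997 rest on F3 replicate 2, whose median correlation with the set was 0.917 (0.960 to 0.971 in the others). saeg-2 lost its call in 6 of 12 alternatives: library totals, the 2 groups alone, the replicate block and each rde-4 library left out (over all alternatives log2 0.93 to 1.76, adjusted p up to 0.373). No gene named here passed in every alternative.

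SID-1 imports double-stranded RNA, and the sid-1 animals asked whether the gonad effect needs it. In sid-1 gonads saeg-2 small RNAs were still higher with pigSi3, 2624 ± 241 CPM against 660.5 ± 45.3 (n = 2 each, log2 1.99, SE 0.248, adjusted p = 0.00833). The difference from the effect in sid-1(+) gonads was -0.40 (adjusted p = 0.619). saeg-1 was at 383 ± 32.5 against 362 ± 48.9 CPM (log2 0.08, adjusted p = 1), with a difference of -1.15 (adjusted p = 0.135) that passed with DESeq2. tbc-8 (4.27), cor-1 (4.09) and C55C3.7 (7.01) were higher and Y48G1BM.9 (-5.44) and pyk-1, a pyruvate kinase gene (-1.93), lower, 66 genes in all (54 higher, 12 lower). The 882 genes lower in N2 at 25 °C had 15 higher and 7 lower in sid-1 gonads (adjusted p = 0.000209, estimated-correlation adjusted p = 0.111). For the difference they had 54 higher and 6 lower (median 0.54, adjusted p = 1.41e-10, estimated-correlation adjusted p = 0.0129). The effect of pigSi3 differed between the backgrounds in 158 genes, 132 with a higher and 26 with a lower log2 ratio in sid-1. Chosen after their values were seen, pde-4 (5.41, adjusted p = 0.000455), Y47D7A.16, now named rft-1 (4.23), ndx-1 (2.73, adjusted p = 0.00142), nhr-64 (-4.81, adjusted p = 0.00148) and his-45 (-2.53) differed. Leaving out a library gave 0 to 11 genes within sid-1 (0 and 11 without sid-1 pigSi3 replicates 2 and 1, 1 and 6 without sid-1 rde-4 replicates 2 and 1) and 51 to 132 for the difference. Within sid-1 saeg-2 did not pass with any 1 of the 4 libraries left out (over all alternatives log2 1.89 to 2.08, adjusted p up to 0.121), and none of the genes named for that background passed in every alternative.

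In neuron mRNA, W04B5.6 was at 12.8 ± 3.67 CPM in WT and 92.6 ± 15.7 in rde-4 (n = 4 each, log2 -2.86, SE 0.293, adjusted p = 0.000781) and W04B5.2 at 24 ± 5.32 against 73.7 ± 22.7 (log2 -1.62, adjusted p = 0.0479). Of 12 ERGO-1 candidates 1 was lower (5 over the list alone), the median was -1.32, and the call held with an estimated correlation (camera adjusted p = 5.16e-07, estimated-correlation adjusted p = 0.00724). C42D4.3 (-5.75) and the globin gene glb-17 (-4.79) were lower in WT, and pud-1.1 (4.001), the receptor guanylate cyclase gene gcy-11 (8.15), the insulin-like gene ins-32 (6.97) and the eggshell chitin synthase gene chs-1 (2.02) were higher. saeg-2 mRNA did not pass (14.9 ± 2.82 against 19.3 ± 7.14 CPM, log2 -0.37, adjusted p = 0.604), nor did egl-4 (log2 0.02, adjusted p = 0.992). Neuropeptide genes had 2 of 126 higher (26 over the list alone, median 0.98, adjusted p = 0.0181, estimated-correlation adjusted p = 0.775), and oocyte markers 1 of 16 higher (adjusted p = 2.81e-05, estimated-correlation adjusted p = 0.48). Genes of other tissues were present too: the muscle gene unc-54 had the most counts in WT replicate 3 (1.94%), and intestine markers are given further below.

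WT and rde-4 neurons differed in 55 of 12693 mRNAs (23 higher, 32 lower, against 40 and 24 with library totals). Of the genes named, W04B5.6 alone passed in every alternative, and rde-4 lost its call in 5 of 16 (over all log2 1.88 to 2.8, adjusted p up to 0.0929). WT replicates 1 and 3 and rde-4 replicate 2 stood apart from the rest, and without these 3, a choice made after seeing the data, 1331 genes passed. Without WT replicate 4 the count was 825 and without WT replicate 1 it was 88, while without WT replicates 2 and 3 and rde-4 replicates 1, 2, 3 and 4 it was 27, 26, 14, 27, 18 and 30. In pigSi3 neurons 3 mRNAs passed, all higher: rde-4, M176.5 (75.4 ± 11 against 8.25 ± 1.9 CPM, log2 3.19, adjusted p = 0.000364) and Y47G6A.29 (log2 2.24, adjusted p = 0.00457). M176.5 passed in every alternative, while Y47G6A.29 did not. saeg-2 (0.21, adjusted p = 0.845) and egl-4 (1.16, adjusted p = 0.594) did not pass. Ribosomal protein genes had a median of -0.93 over 83 members with none called (adjusted p = 1.82e-12, estimated-correlation adjusted p = 0.716) and neuropeptide genes one of -0.65 (adjusted p = 1.91e-07, estimated-correlation adjusted p = 0.716). Without the 3 libraries that stood apart, 1380 genes passed, and egl-4 passed in WT (1.27) and in pigSi3 (1.54).

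In gonad mRNA, saeg-2 fell with neuronal RDE-4 to 4.39 ± 0.672 from 55.2 ± 4.82 CPM (n = 3 each, log2 -3.64, SE 0.387, adjusted p = 0.000784). saeg-1 (-1.72, adjusted p = 0.474), egl-4 (0.17, adjusted p = 0.909), sid-1 (0.10, adjusted p = 0.93) and the nuclear Argonaute gene hrde-1 (0.05, adjusted p = 0.978) did not pass. C32D5.8 rose from 2.28 ± 0.35 to 48.9 ± 3.98 CPM (log2 4.37, adjusted p = 1.03e-08) and C32D5.18 by 4.54. Histone mRNAs had 9 of 53 higher (22, with 2 lower, over the list alone, median 0.53, adjusted p = 5.57e-14, estimated-correlation adjusted p = 0.683), among them his-63 (2.94), his-60 (2.77), his-59 (2.45) and his-45 (2.44). T28F2.1 (-4.31), K10G9.2 (-3.36), the calcium channel subunit gene ccb-1 (-2.70) and ins-5 (-1.55) fell. Sperm markers, which vary between these dissected gonads, had a median of -1.13 over 21 members (adjusted p = 0.000236, estimated-correlation adjusted p = 0.683) and major sperm protein genes one of -0.998 (adjusted p = 1.67e-05, estimated-correlation adjusted p = 0.683). Of 10569 mRNAs 51 passed (13 higher, 38 lower), with 24, 21 and 23 without pigSi3 replicates 1, 2 and 3 and 33, 29 and 27 without rde-4 replicates 1, 2 and 3. saeg-2, C32D5.8, C32D5.18 and his-60 passed in every alternative. With the sperm marker level as a covariate, chosen after the results were seen, the histone median was 0.34.

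Small RNAs and mRNA of the gonad were then set side by side over 7931 genes tested in both. Of these, saeg-2, Y102A5C.6, Y41C4A.12 and Y55F3BR.2 had more small RNAs and less mRNA in pigSi3 (4 genes, 0.187 for independent lists). C17H11.2, C32D5.8, his-45, his-59 and his-63 had more of both (5, 0.0624), F33H2.3, R01H10.4 and T28F2.1 had less of both (3, 0.337), and no gene had fewer small RNAs with more mRNA (0.112 for independent lists). Genes with fewer small RNAs (81) had less mRNA as a list, with a median of -0.60 and 3 lower (12 over the list alone, adjusted p = 1.08e-13, estimated-correlation adjusted p = 0.000189). Genes with more small RNAs (45) had 5 higher and 4 lower (adjusted p = 0.36).

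Gonad mRNA of pigSi3 F3 differed broadly from rde-4. Ribosomal protein genes were higher in 73 of 82 (77 over the list alone, median 0.90, adjusted p = 1.15e-27, estimated-correlation adjusted p = 0.794). Examples were rpl-19 (4024 ± 338 against 1532 ± 138 CPM, log2 1.39), rpl-26 (1.13) and rps-13 (0.93). Histone genes were higher in 27 of 53 (28 over the list alone, adjusted p = 4.68e-12, estimated-correlation adjusted p = 0.794), his-60 at 2.88. The germ cell RNA regulators fbf-1 (-1.94) and fbf-2 (-1.91), the P granule genes glh-1 (-1.68) and pgl-1 (-0.91), the yolk receptor gene rme-2 (-2.03), chs-1 (-1.94) and mes-6 of the Polycomb complex (-2.27) were lower. So were somatic genes such as icl-1 (-3.38), myo-1 (-2.95), vit-5 (-2.45) and unc-54 (-2.23). Small RNA pathway genes had 25 of 66 lower and 2 higher (26 and 3 over the list alone, adjusted p = 0.00022, estimated-correlation adjusted p = 0.889), including rde-10 (-1.58) and wago-2 (-1.13). Germline markers (9 of 24 lower, 3 higher, adjusted p = 0.0288, estimated-correlation adjusted p = 0.889) and oocyte markers (7 of 16 lower, adjusted p = 0.005, estimated-correlation adjusted p = 0.889) were lower as lists with the preset correlation only. saeg-2 mRNA was at 21.6 ± 14 CPM (log2 -1.34, SE 0.348, adjusted p = 0.0111), with egl-4 (-0.92, adjusted p = 0.000707), hrde-1 (-0.72, adjusted p = 0.00202) and sid-1 (-0.54, adjusted p = 0.00596) also lower. Sperm markers had a median of 0.95 over 21 members, with 0 higher and 1 lower. Of 10569 genes 2961 passed (1434 higher, 1527 lower, and 2072 and 1052 with library totals, a shift of 0.186 in the median of all genes). With the sperm marker level as a covariate, chosen after the results were seen, 3457 genes passed, and 34 histone genes were higher. saeg-2 did not pass with the 2 groups alone or without F3 replicate 1 (over all alternatives log2 -1.97 to -0.91, adjusted p up to 0.0563).

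In sid-1 gonads saeg-2 mRNA fell with pigSi3 to 3.78 ± 1.27 from 47.4 ± 4.63 CPM (n = 3 each, log2 -3.69, SE 0.413, adjusted p = 0.00579), and the difference from the sid-1(+) effect was -0.05 (adjusted p = 0.994). T23G5.9 (-4.54), Y37A1B.17 (-1.50) and tcl-2 (-1.11) were lower, and C55C3.3 (3.13), C17H11.2 (1.73), wdfy-3 (1.66) and sop-2, a gene of Polycomb-like silencing (1.42), higher. saeg-2 was the gene with more small RNAs and less mRNA in this background too (1 gene, 0.0132 for independent lists). C17H11.2, cnk-1, umps-1 and ymel-1 had more of both (4, 0.0353) and Y37A1B.17 had less of both (1, 0.00265). Histone mRNAs had none called (1 higher and 22 lower over the list alone, median -0.71, adjusted p = 5.59e-12, estimated-correlation adjusted p = 0.597). Sperm markers had a median of 2.73, or 2.49 with the genes at 0 in a group set to the floor (adjusted p = 1.5e-05, estimated-correlation adjusted p = 0.716). The effect of pigSi3 differed between the backgrounds in 44 mRNAs (30 higher, 14 lower in sid-1). Chosen after their values were seen, C32D5.8 (-4.48, adjusted p = 2.12e-07), his-60 (-3.83, adjusted p = 5.34e-05), his-63 (-4.02), wdfy-3 (3.16) and K10G9.2 (6.51) had differences among those with the smallest adjusted p. Within sid-1 13 genes passed (9 higher, 4 lower), with 96 without sid-1 pigSi3 replicate 3, 0 and 8 without its replicates 1 and 2, and 1, 1 and 8 without sid-1 rde-4 replicates 1, 2 and 3. The difference gave 15 to 181 genes as libraries were left out. The other genes named within sid-1 lost their calls in 4 (C17H11.2, wdfy-3) to 8 (C55C3.3) alternatives. saeg-2 did not pass there without sid-1 pigSi3 replicate 1 (over all alternatives log2 -3.99 to -3.45, adjusted p up to 0.0522). With the sperm marker level as a covariate the histone median was -0.33 within sid-1 and -0.66 for the difference, against -1.24 without it.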

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

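The splits of libraries into other groups and the tests of the genes shared by pigEx10 generations and of somatic RNA in F3 gonads, and the permutations, were chosen after the results were seen. The tests of depth, batch and sperm address patterns seen in the results too, but their predictions were written before these tests were run.

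In neuron mRNA, rde-4 replicate 2 lay far from the other 3 rde-4 libraries: 47.2% of its reads were in genes (43.0 to 43.5% in the others), its median correlation with the other libraries of its group was 0.866 (0.916 to 0.920), and heat shock and stress genes summed to 207700 CPM (37370 to 58930). pigSi3 replicate 4 had a median correlation with its group of 0.927 (0.951 to 0.953) and 15240 CPM in the promoter genes of the transgene reporters (9593 to 10480). These 5 stood out among all groups and measures looked at, where 5.2 would stand out by chance. The rule sought 1 library far from the rest of its group, so it can miss a group with more than 1 such library. It did not flag WT neuron mRNA replicates 1 and 3, whose median correlations with the neuron mRNA libraries were the lowest of that set. The comparison with chance thus does not cover them.

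The effect of losing rde-4 differed between 25 and 20 °C in 272 small RNA genes, with saeg-2 at a log2 difference of 1.91. The effect of pigSi3 on gonads differed between sid-1 mutant and sid-1(+) animals in 158 genes for small RNA and 44 for mRNA.

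Regrouping the same libraries puts a bound on chance only where enough splits exist. With 10 splits the smallest share is 1 in 10, which cannot exclude chance. For N2 and pigSi3 at 20 °C, pigEx10 P0, F1 and F3, N2 at 25 °C and gonad mRNA of pigSi3, pigSi3 F3 and sid-1 pigSi3, only 10 splits exist and 1, the real one, gave as many calls (4016, 750, 202, 40, 40, 1738, 51, 2961 and 13 genes), the highest other being 0, or 2 for pigSi3 F3. For pigEx9 F1 and F3, 2 of 10 splits gave as many calls as the 19 and 6 genes observed. The highest other values there were 434, with the failed F1 library grouped with rde-4 replicates 4 and 5 and 36, with the shallow F3 library grouped with them. These splits still part the other F1 or F3 libraries from those controls, so they lie close to the real grouping and do not bear on chance. In run 1 the replicate pairing leaves 3 other splits that part as many pairs as the real one, and their highest count was 0. For pigEx9 P0 1 of 100 splits, the real one with 730 genes, gave as many (highest other 95), and for pigSi3 neuron mRNA 1 of 35 (3 genes, of which rde-4 is the transgene itself and 2 are others, highest other 0), so the tables argue against chance there. For pigSi3 F3 whole animals 7 of 100 splits gave at least 2 genes (highest other 1657). The others all group rde-4 replicates 4 and 5 or 6 and 7, which share a run. That share thus carries differences between runs and does not bear on chance. For WT neuron mRNA 3 of 35 gave at least 55 (1862, with WT replicates 1 and 3 grouped with rde-4 replicates 3 and 4), so this count is within what regrouping yields. For the temperature difference 7 of 100 gave at least 272 (576). The 6 others all keep N2 and rde-4 apart at 25 °C and so carry that effect, so this share does not bear on chance. For the sid-1 difference in gonad mRNA it was 3 of 100, yet another split gave 670 against 44, so the libraries hold structure of another origin.

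Carriers, F1 and F3 of pigEx10 share 28 called genes, C55C3.7, Y59C2A.1, C53D5.5, Y39B6A.41 and T23F6.3 among them. Of these, 12 move the same way in pigEx9 P0 against its own controls (exact binomial p = 0.572, 3 called the same way and 0 the other), which argues against an effect of neuronal rde-4 shared by both arrays as the cause for most of them. In pigSi3 whole animals 11 do (p = 0.345), and in pigSi3 F3 22 do, a number that the 3 controls of run 4, shared by both comparisons, raise by themselves. Another explanation is that the 3 rde-4 libraries of run 4 stand apart from the other rde-4 libraries. In 12 genes only the mean of these lies outside the range of the other 8, and in 7 genes only the F3 mean does (exact binomial p = 0.359), so an inherited change of this line and a shift of these controls cannot be told apart.

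Gonad mRNA of pigSi3 F3 differs from rde-4 in 2961 genes, with ribosomal protein genes higher and germ cell genes such as fbf-1, glh-1 and rme-2 lower. With every library thinned to the smallest total, 2746062 counts, 2550 genes were called (2600 and 2605 in other draws), which argues against depth. Of 40 germline and oocyte markers 16 were lower and 3 higher, and of 61 somatic markers 17 were lower and 1 higher, which argues against a change in the share of somatic RNA as the whole cause. A batch that the F3 libraries share stays open, since at least 66.9% of the calls went the same way against each other gonad group, as both a batch and an effect of the F3 state would give. An effect of the generation was not tested apart from it.

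Genes with fewer small RNAs in pigSi3 gonads (81) also had less mRNA there, with a median log2 difference of -0.60. Sperm content varies between these dissections. With the sperm marker level as a covariate the median was -0.42 (quartiles -0.87 to -0.14, camera p = 1.01e-11 over genes and 0.000156 with an estimated correlation, permutation p over the 10 splits of the libraries 0.1, the lowest they can give), which argues against sperm as the whole cause. In the sid-1 background the median was 0.27 (camera p over genes 0.00101, permutation p = 0.1 over 10 splits). The bound set before this test would exclude an effect that needs no difference in sperm, but it was wrongly drawn. Small RNAs of the same genes did not fall there either (median 0.33), so that contrast cannot decide. That explanation stays open.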

How the results depend on the processing

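The fits without the shallow pigEx9 libraries and without 3 neuron mRNA libraries, the crossed pairing and the sperm covariate were chosen after the results were seen. Of the alternatives for the named genes 3732 left the gene on its side of the threshold, 381 lost and 17 gained a call, and 2 reversed: T23F6.3 with all 11 rde-4 libraries as controls, at -0.33 in pigEx10 F1 and -0.85 in F3. Fewer libraries or genes explain part of the changes by construction; for the rest the cause was not tested.

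Counts of called genes moved by more than 1.5 times as follows. With DESeq2 they were 34 and 17 (pigEx9 F1, F3), 332, 143 and 125 (pigEx10 P0, F1, F3), 221 (pigSi3 F3 whole), 795 (temperature difference), 515, 377, 151 and 404 (gonad small RNA of pigSi3, F3, sid-1 and their difference), 862 and 114 (neuron mRNA of WT, pigSi3) and 110, 134 and 186 (gonad mRNA of pigSi3, sid-1, difference). With no filter they were 11 (pigEx9 F3), 64 (pigEx10 F3), 9 (pigSi3 F3 whole), 135 (pigSi3 neurons), 365, 181, 102 and 247 (gonad small RNA, same order) and 8 (pigSi3 neuron mRNA). With a mean count of at least 50 they were 476 and 2 (pigEx9 P0, F3), 6 (pigSi3 F3 whole), 146 (pigSi3 gonads) and 9 (pigSi3 neuron mRNA). With only the 2 groups fitted they were 438, 417 and 64 (pigEx9 P0, F1, F3), 388 (WT neurons), 440, 0 and 202 (gonad small RNA of pigSi3, F3, sid-1), 4 and 296 (neuron mRNA) and 10 and 5 (gonad mRNA of pigSi3, sid-1).

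With all 11 rde-4 libraries as controls the counts were 457 (pigSi3), 21 (pigEx9 F3), 664, 3 and 2 (pigEx10 P0, F1, F3). In run 2 alone they were 1523, 376 and 300 (pigEx9 P0, F1, F3) and in run 3 alone 165 (P0). Without the 2 shallow libraries they were 7 and 2 (pigEx9 F1, F3). For pigSi3 F3 whole animals they were 0, 27, 2945 and 2936 with rde-4 replicates 1 to 3, 4 and 5, 6 to 8 and 9 to 11. Without the 3 neuron mRNA libraries that stand apart they were 1331 (WT) and 1380 (pigSi3).

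In run 1 the replicate block gave 1554 genes for pigSi3 and 6014 for N2 (3118 higher, 2896 lower). Among the named genes and fixed lists it changed only the calls given with the results. Elsewhere libraries share a number only, with median correlations of 0.04 (25 °C, 2 of 6 closest to their own number), 0.22 (both temperatures, 11 of 12), -0.10 (neurons, 4 of 6), -0.06 (gonads, 4 of 10), 0 (neuron mRNA, 3 of 12) and -0.04 (gonad mRNA, 1 of 15). The block gave 110 and 2 (gonad small RNA of pigSi3, F3), 26 (WT neuron mRNA), 7 and 25 (gonad mRNA of sid-1, difference). In sid-1 gonads a crossed block gave 349 genes, against 135 with the plain block of these groups. No paired analysis was possible for pigEx9 and pigEx10, whose groups share at most 1 replicate number with the controls of their run, and for whole pigSi3 F3 animals, which come from another run than any control.

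Where a group of 2 loses a library, 1 stays and the other groups of the fit supply the spread. Lowest and highest counts with 1 library left out were 2657 and 3589 (N2 at 20 °C), 369 and 603 (pigSi3), 485 and 952, 0 and 21, 2 and 12 (pigEx9 P0, F1, F3), 123 and 184, 19 and 61, 12 and 45 (pigEx10 P0, F1, F3), 1 and 10 (pigSi3 F3 whole), 815 and 2084 (25 °C), 1.2e+02 and 572 (temperature difference), 142 and 432, 72 and 111 (neurons of WT, pigSi3), 33 and 135, 0 and 3997, 0 and 11, 51 and 132 (gonad small RNA), 14 and 825 (WT neuron mRNA), 21 and 33, 0 and 96, 15 and 181 (gonad mRNA of pigSi3, sid-1, difference).

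With an estimated correlation, list tests lost their call in pigSi3 whole animals (adjusted p = 0.327 and 0.12 for genes higher and lower in N2 at 25 °C, 0.327 for each neuron list), in pigEx9 P0 (0.0575, genes higher in WT neurons), in pigSi3 neurons (0.0794, genes lower in WT neurons), for the lists from 25 °C and from neurons in pigEx9 F1 (0.978, also 0.23 with library totals) and F3 (0.748 each), for genes lower in N2 at 25 °C in sid-1 gonads (0.111), and for genes lower in run 3 carriers in pigEx9 F1 (0.896) and pigEx10 F1 and F3 (0.0508 and 0.159). Genes lower in WT neurons also lost theirs in pigSi3 gonads (0.444) and F3 gonads (0.424), as did genes higher in N2 at 25 °C in F3 gonads (0.424). With library totals, genes lower in N2 at 25 °C passed in F3 gonads (adjusted p = 0.0243). Over all 539 list tests, library totals ended 14 calls and gave 12, most of them not named here. With the 200 genes of smallest p as the list, genes with more small RNAs in pigSi3 gonads passed in mRNA (adjusted p = 0.0359, estimated-correlation adjusted p = 0.447).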

Other observations

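Several genes had more small RNAs in rde-4 than in other strains in more than a single tissue. dpf-6, ndx-1, pde-4 and T28F2.1 were lower in N2 at both temperatures or in WT neurons, and pde-4 and ndx-1 were also lower in pigSi3 neurons and gonads. Y110A2AL.1 was higher in pigSi3 whole animals, neurons and gonads. These genes were chosen after their values were seen, and overlaps between tissues were not tested.

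In N2 against rde-4 at 20 °C the histone (adjusted p = 0.419), ribosomal protein (0.557), F-box (0.551), heat shock (0.551), immune response (0.485), synaptic vesicle (0.665), neuropeptide (0.2), intestine (0.189), glia (0.349), muscle (0.189), somatic gonad (0.419), oocyte (0.17) and sperm (0.189) lists did not pass. Major sperm protein genes had 8 of 23 lower in N2 (adjusted p = 0.00238, estimated-correlation adjusted p = 0.594), and near-identical copies make their counts uncertain. Intestine markers had a median of 0.998 in pigEx9 P0 with none called (adjusted p = 5.28e-05, estimated-correlation adjusted p = 0.578) and of 1.44 in WT neuron mRNA (adjusted p = 0.000558, estimated-correlation adjusted p = 0.533). In pigSi3 neuron mRNA, heat shock genes had a median of -1.02 (adjusted p = 0.000268, estimated-correlation adjusted p = 0.361), which shrank to -0.42 without rde-4 replicate 2, the library with 207700 CPM in them. There, synaptic vesicle genes had a median of 0.39 (adjusted p = 0.00467, estimated-correlation adjusted p = 0.716) and somatic gonad markers one of 0.82 (adjusted p = 0.0353, estimated-correlation adjusted p = 0.361). Muscle markers had a median of 0.90 in sid-1 pigSi3 gonad mRNA (adjusted p = 1.5e-05, estimated-correlation adjusted p = 0.597).

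The mean log2 CPM of sperm markers by gonad mRNA library was 3.56, 1.97 and 3.79 in rde-4, -0.18, 2.29 and 3.26 in pigSi3, 3.51, 4.35 and 3.84 in pigSi3 F3, 0.26, -0.25 and 2.17 in sid-1 rde-4, and 3.02, 4.51 and -0.06 in sid-1 pigSi3. Of the genes that moved in pigSi3 F3 gonads, his-45, his-56, his-61 and his-63 had more small RNAs and more mRNA (4 genes, 1.65 for independent lists), and elks-1, saeg-2 and T16G12.3 had more small RNAs and less mRNA (3, 1.81).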
